A study of Mus musculus with 14 samples.

How the data were processed

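RNA was measured by sequencing in 14 libraries of sorted mouse cells. Adult mice carried a tamoxifen-inducible Cre recombinase at the Tert locus and a tdTomato reporter that Cre switches on, and cells of the submandibular gland, a salivary gland, were sorted as negative for the dye DAPI and positive for EpCAM, a surface protein of epithelial cells. The labels call tdTomato-positive cells Tert+ and tdTomato-negative cells Tert-. Some mice received 15 Gy of radiation (RT), and the time from RT to sorting is not given in the labels. Libraries were made from 1 ng of RNA each with a protocol the labels credit to Picelli.

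Groups followed the sample titles, which matched the descriptions in 14 of 14 libraries. A further label field for the cell type stated the opposite population in 14 of 14 libraries, so the direction of each Tert+ against Tert- difference rests on the titles. Libraries are named here by title and replicate. The 4 groups were Tert+ without RT (n = 3), Tert- without RT (n = 3), Tert+ after RT (n = 4) and Tert- after RT (n = 4). The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries. All libraries after RT carry higher library numbers than those without RT.

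The deposited table holds counts of reads per gene, 1 column per library, without normalisation. The submitters' processing notes name the aligner HISAT2, without a version, and the mouse genome build mm10; the counting program and the annotation release are not stated. The table also gives each gene's length in bases, per the file headers. Of 54532 genes in the table, 54409 identifiers were found in the GENCODE annotation provided and 53499 had the same chromosome, start and end there. Gene positions are those of the table on mm10. How reads shared between gene copies were counted is not stated, so values of kallikrein, histone, immunoglobulin, ribosomal protein and mitochondrially encoded genes, which have close copies, are less certain. The table has no entry for tdTomato. Total counts per library ran from 5520412 to 15943597, and 16289 to 19210 genes had a count. Counting intervals and the lower bounds used for genes at 0 cover counting error only, since reads without molecular identifiers are not independent molecules.

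Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr on the 4 groups, which left 15915, and scaled with TMM factors. A model with 1 term per group was fitted over all 14 libraries with robust dispersions, and quasi-likelihood F tests, which are two-sided, gave p-values that were adjusted over all genes tested by the method of Benjamini and Hochberg. The threshold was an adjusted p of 0.05. Expression is given as CPM, each count divided by its library's TMM-scaled total and put on edgeR's common scale. All log2 fold changes and adjusted p-values come from edgeR unless another tool is named. Groups are given as mean CPM ± SD. For a gene at 0 in all libraries of a group, the fold is a lower bound computed from 3 counts over the group. For a gene with 1 to 3 counts in a group, the ratio of group counts is given with its 95% counting interval (exact, Clopper-Pearson). The 5 comparisons were Tert+ against Tert- without RT, the same after RT, RT against no RT in Tert+, the same in Tert-, and the difference of the last pair. Tert itself was also compared with exact two-sided permutation tests of CPM.

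Before the data were examined, groups, tests, 39 gene lists and the rule for naming genes were fixed. Of the lists, 37 had at least 3 tested members; of 791 listed symbols, 1 was not matched. Lists were tested with camera at a preset correlation between genes of 0.01 and adjusted over the 37 lists within a comparison. Each was also tested with camera at an estimated correlation, and with fry of limma 3.58.1, whose directional test asks whether the members move on balance one way and whose mixed test asks whether they change in either direction. None of the calls made at the preset correlation for these 37 lists held with an estimated correlation. Members were counted past the threshold over all genes and adjusted over the list alone. A further 7 lists of immune cell genes (mature B cell, germinal centre B cell, plasma cell, macrophage, T cell, dendritic cell, and monocyte and neutrophil) were written after the gene tables had been seen, adjusted over those 7, and used in the closing section.

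The named genes were Tert first. Then came, per comparison, up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups. Per list, up to 4 members past the threshold were named, or, where none passed, the 2 with the highest expression as values. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p were added. Predicted genes, unnamed loci and pseudogenes were counted and not named. Genes outside this rule are said to have been chosen after their values were seen.

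Replicate numbers were checked as possible pairs over 9321 genes, by correlating each library's deviations from its group mean with those of the library of the same number in the other population. Without RT the correlations across genes were 0.288, 0.307 and 0.116. Replicates 1 and 2 correlated best with their own number, while replicate 3 correlated better with another number (0.149). The labels state no pairing, so the numbers may pair the samples there, but this is not settled. Genes are not independent replicates in these correlations.

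The scaling, the gene tests and camera were tested on simulated data with known changes among 15915 genes, without the filter or the naming rule. Counts were drawn independently for each gene from the fitted spread. The simulation thus held no correlation between genes, no outlying library and no batch, and its rates do not cover these. At a true 4-fold change, edgeR called 37.3% of changed genes for Tert+ against Tert- without RT, 44.8% after RT, 50.7% and 46.3% for RT in Tert+ and in Tert-, and 43.3% for the difference of the RT effects. At most 4 unchanged genes were called in any of these 5 comparisons. Alternatives tried were RLE and upper quartile scaling, no filter, a stricter filter, thinning to the smallest total, DESeq2 1.42.0, limma voom with quality weights, a test against a 1.5-fold change, a fit of only the groups compared, a replicate block, leaving out mitochondrially encoded genes, and leaving out each library in turn. Alternatives added after seeing the data left out the 2 libraries least correlated with their groups, left out acinar and granular convoluted tubule genes, added an epithelial covariate, or applied a loess offset for GC content and gene length. No library was left out of the reported values. Some genes past the threshold are counted but not reported here by name.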

Results

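The 14 libraries held sorted cells of the mouse submandibular gland, with 3 libraries each of Tert+ and Tert- cells without RT and 4 of each after 15 Gy. Total counts ran from 9220126 to 15943597 in Tert+ without RT and from 9687159 to 13454637 in Tert- without RT. After RT they ran from 5986984 to 11642156 in Tert+ and from 5520412 to 10953634 in Tert-. The first principal component, 17.8% of the variance, separated libraries with and without RT, and the second, 11.9%, set Tert+ after RT replicate 4 apart from the rest. Each library's median rank correlation with its own group lay between 0.912 and 0.946. In Tert+ without RT replicate 1, acinar genes took 3.89% of counts and the 10 most abundant genes 17.9%. Of 20 exact two-sided permutation tests of library measures between groups, the smallest adjusted p was 0.327. Such tests of Tert+ against Tert- without RT cannot give an unadjusted p under 0.1, which the mitochondrial and granular convoluted tubule shares reached. The immunoglobulin share after RT, 1.86% in Tert+ and 1.48% in Tert-, was at its smallest possible unadjusted p of 0.0286 (exact permutation).

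Tert (ENSMUSG00000021611, chromosome 13, 73626911 to 73649843), the catalytic subunit of telomerase and the locus that carries the Cre, was counted at 0 to 52 reads per library. Since tamoxifen-induced Cre switches the reporter on, tdTomato at sorting need not track Tert RNA at sorting. Without RT it was 0.350 ± 0.314 CPM in Tert+ libraries and 1.81 ± 0.566 CPM in Tert- libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows), the opposite of the order in the titles. Its counts without RT were 0, 7 and 8 in Tert+ and 22, 28 and 13 in Tert-. After RT it was 3.58 ± 3.76 CPM in Tert+ and 0.621 ± 0.718 CPM in Tert- (SD, n = 4 each; exact permutation p = 0.257), with counts of 0, 52, 34 and 15 against 0, 0, 9 and 15. With RT the exact permutation p was 0.257 in Tert+ and 0.0857 in Tert-, where the smallest possible with 3 against 4 is 0.0286. These 4 tests formed 1 family, with adjusted p-values of 0.2 to 0.257. edgeR put Tert past the threshold in none of the 5 comparisons.

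Genes of B lymphocytes were counted above the epithelial genes Epcam, Krt8 and Krt18 in the 14 libraries. Cd74 and H2-Ab1, which serve antigen presentation on major histocompatibility complex class II, took mean shares of 2.71% and 1.67% of counts, and Ighm, the immunoglobulin mu chain, 0.598%. The B cell genes Cd79a and Ms4a1 had median levels of 2794 and 1686 CPM over the 14 libraries, and Ptprc, the leukocyte surface protein CD45, 1369.9 CPM. Epcam, the protein used for sorting, had a median of 43.6 CPM, and the epithelial keratins Krt8 and Krt18 had 49.5 and 94.1 CPM. Secretory products of the gland were abundant as well, with median levels of 1984 CPM for the kallikrein Klk1 and 1327 CPM for the mucin-like Smgc. The acinar list took a median of 1.13% of counts, and the granular convoluted tubule list 0.408%. Xist was counted in 14 of 14 libraries and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y in 0. The genes of this paragraph were chosen after their values were seen.

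**Figure D1:**
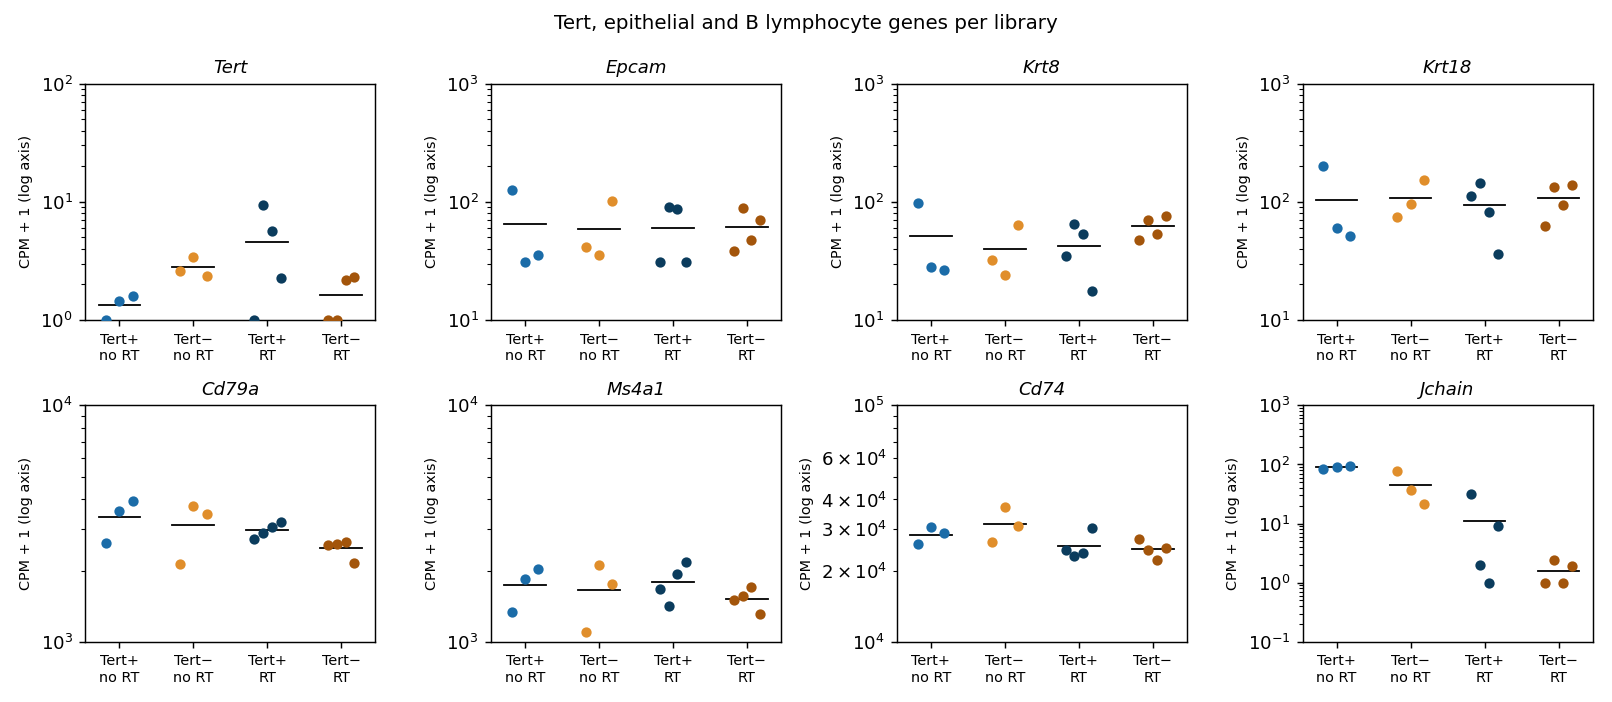
CPM plus 1, on a log axis, of Tert and of epithelial and B lymphocyte genes, with 1 point per library and a line at each group's mean. Cd79a, Ms4a1 and Cd74 lay above Epcam, Krt8 and Krt18 in the 14 libraries, with medians of 2794 CPM for Cd79a and 43.6 CPM for Epcam.

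The first comparison asked how Tert+ and Tert- cells differed in glands without RT. C1qc, a chain of the complement component C1q, and Ms4a7, Axl, Itgb5 and Apoe were lower in Tert+ libraries. Ms4a7 (ENSMUSG00000024672, chromosome 19, 11321039 to 11336146), a membrane protein, was at 1.33 ± 0.949 against 61.9 ± 8.63 CPM (SD, n = 3 each) and fell by 5.54 on the log2 scale (adjusted p = 0.00503). C1qc (ENSMUSG00000036896, chromosome 4, 136889804 to 136893065) was at 5.48 ± 6.96 against 321 ± 35.1 CPM and fell by 5.98 on the log2 scale (adjusted p = 0.0433). Axl (ENSMUSG00000002602, chromosome 7, 25757273 to 25788705), a receptor for clearance of dying cells, was at 6.59 ± 1.82 against 107 ± 36.4 CPM. Itgb5 (ENSMUSG00000022817, chromosome 16, 33829665 to 33949338), an integrin subunit, was at 13.8 ± 6.12 against 113 ± 24.9 CPM, and both had an adjusted p of 0.0141. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), a lipid carrier, was at 411 ± 122 against 1559.8 ± 249 CPM (adjusted p = 0.0433).

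These genes were 5 of the 6 past the threshold without RT, with 6 lower and 0 higher in Tert+ libraries. edgeR gave 716 genes an unadjusted p under 0.05, DESeq2 called 2 higher and 72 lower, and limma voom called 3 higher and 30 lower. Since Tert ran against the titles without RT, the direction rests on the titles. With a block for the replicate numbers, 7 genes passed, 5 of them shared. Of the 6, Ms4a7 alone kept its call in each of the 14 leave-outs. The count was 3 without Tert+ no RT replicate 2, 1 without Tert+ no RT replicate 3, 3, 3 and 2 without Tert- no RT replicates 1, 2 and 3, 13 and 10 without Tert+ RT replicates 3 and 4, and 3 without either Tert- RT replicate 2 or 3. Ranges did not overlap for 8.87% of genes, where chance gives 10% if the libraries are not paired.

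**Figure D2:**
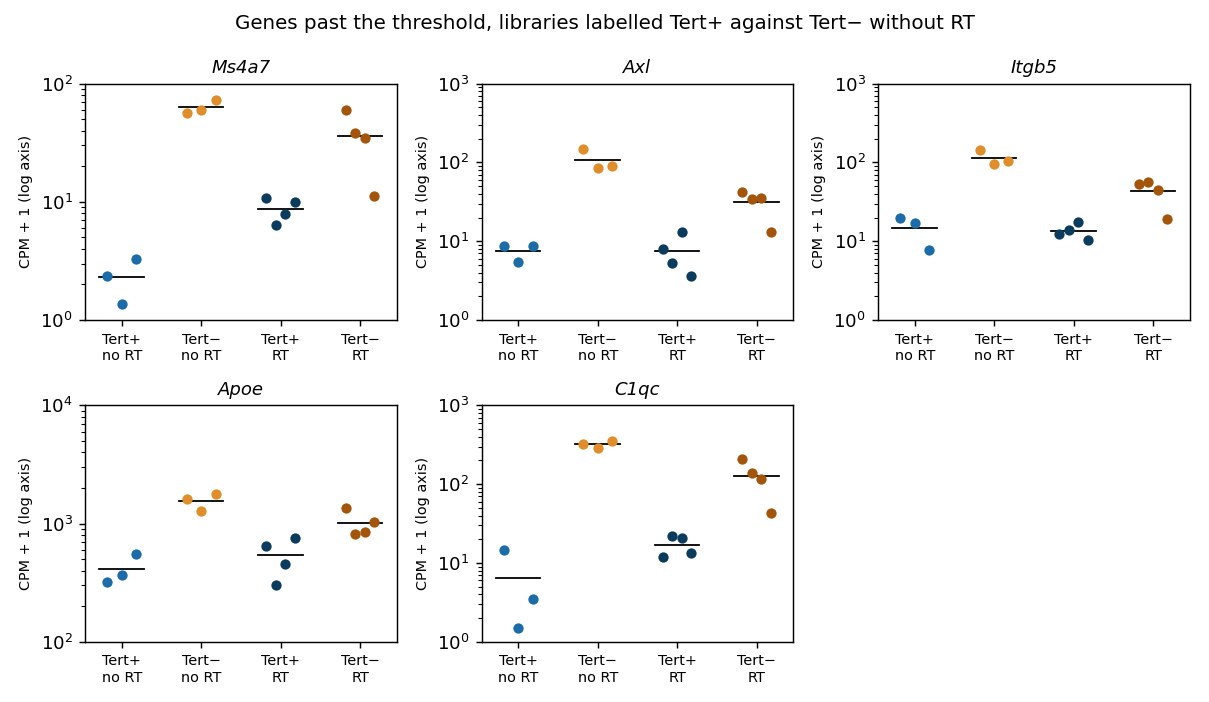
CPM plus 1, on a log axis, of 5 of the 6 genes past the threshold in Tert+ against Tert- libraries without RT, with 1 point per library and a line at each group's mean. The 3 Tert+ libraries without RT lay below the 3 Tert- libraries for each gene, with means of 1.33 and 61.9 CPM for Ms4a7.

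Among the gene lists without RT, the immune cell list was called lower in Tert+ libraries although its members went both ways, 11 higher and 13 lower, with a median log2 fold change of -0.21. Of these 24 genes 1 fell, 23 did not pass, and 5 fell when adjusted over the list alone. The immune cell list had a camera adjusted p of 3.6e-04, and adjusted p = 0.397 with an estimated correlation, a fry directional adjusted p of 0.536 and a fry mixed adjusted p of 5.1e-05. The 5 that fell over the list alone were C1qa, C1qb, C1qc, Csf1r and Adgre1, with C1qa at 8.03 ± 11.8 against 393 ± 81.6 CPM and C1qb at 5.34 ± 8.39 against 409.7 ± 37.7 CPM. Lyz2, a lysozyme on the same list, was at 993 ± 602 against 486 ± 213 CPM and did not pass. The immune call ended without Tert- no RT replicate 1 (adjusted p = 0.0574). Of 20 granular convoluted tubule genes, products of the gland's ducts such as kallikreins and growth factors, 20 had lower fold changes and 0 passed, over all genes or adjusted over the list alone. The tubule list had a camera adjusted p of 4.1e-12, and adjusted p = 0.397 with an estimated correlation. Klk1 was at 2642 ± 1833 against 6956 ± 5381 CPM and Klk1b26 at 335 ± 269 against 1376 ± 921 CPM. The share of counts from this list was 0.333% in Tert+ and 1.02% in Tert- libraries.

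The senescence and secreted inflammatory factor list was lower without RT, with 0 of 19 past the threshold over all genes and 6 falling when adjusted over the list alone, among them Il1a, Cxcl2, Cxcl10, Ccl2 and Tnf. The inflammatory factor list had a camera adjusted p of 1.6e-05, and adjusted p = 0.397 with an estimated correlation. These 5 genes encode cytokines and chemokines, and the call ended without Tert- no RT replicate 1 (adjusted p = 0.249). Mitochondrially encoded transcripts were lower in 14 of 15 members with 0 past. The mitochondrial transcript list had a camera adjusted p of 1.6e-07, and adjusted p = 0.397 with an estimated correlation. Its member mt-Co1 was at 2441 ± 1451 against 4130.2 ± 1022 CPM. Cell cycle genes were higher in 33 of 42 members with 0 past. The cell cycle list had a camera adjusted p of 3.6e-04, and adjusted p = 0.397 with an estimated correlation. That call ended without Tert- no RT replicate 3 (adjusted p = 0.0522). Immediate early genes were lower in 24 of 28 members with 0 past. The immediate early list had a camera adjusted p of 3.6e-04, and adjusted p = 0.706 with an estimated correlation. The call ended without Tert+ no RT replicate 3 (adjusted p = 0.296) and Tert- no RT replicate 1 (0.772). Of 13 Notch pathway genes 0 passed and Jag1 fell when adjusted over the list alone. The Notch list had a camera adjusted p of 0.0122, and adjusted p = 0.397 with an estimated correlation. This call ended without the same libraries (0.117 and 0.278). None of these 4 lists had another member past when adjusted over the list alone. The NF-kB target and fibroblast lists were called lower by camera at adjusted p = 0.0360 and 0.0346, with 0 of 22 and 0 of 10 members past, and both had adjusted p = 0.706 at an estimated correlation. These 2 calls held in 5 and 7 of 14 leave-outs, with adjusted p-values up to 0.974 and 0.772, both without Tert- no RT replicate 1. Of 18 salivary progenitor genes and 19 telomerase and shelterin genes, 0 passed and neither list was called (camera adjusted p = 0.802 for both).

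The second comparison asked the same of Tert+ and Tert- cells after RT, and single genes parted them. P2ry6 (ENSMUSG00000048779, chromosome 7, 100937630 to 100974649), a receptor for extracellular nucleotides, had 3 counts in the 4 Tert+ libraries and 403 in the 4 Tert- libraries, 51.7-fold to 741-fold lower by its counting interval (adjusted p = 0.0177). Ly6c2 (ENSMUSG00000022584, chromosome 15, 75108158 to 75111970), a leukocyte surface protein, rose to 58.2 ± 13.8 against 7.57 ± 2.51 CPM (SD, n = 4 each; adjusted p = 0.0308). The next 3 genes did not pass. Gsr, glutathione reductase, was at 22.6 ± 4.51 against 3.91 ± 1.59 CPM (adjusted p = 0.0649). Gatm, an enzyme of creatine synthesis, was at 1.29 ± 1.88 against 23.6 ± 13.8 CPM and Gpatch1 at 8.21 ± 2.23 against 24.1 ± 1.90 CPM (adjusted p = 0.186 for both). The C1q genes were not past over all genes here and fell when adjusted over the immune cell list alone, with C1qa at 24.3 ± 14.6 against 166.9 ± 86.9 CPM.

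P2ry6 and Ly6c2 were the 2 genes past the threshold in edgeR, 1 lower and 1 higher, with 1176 at an unadjusted p under 0.05. DESeq2 called 109 and limma voom 0. Neither of the 2 kept its call in each leave-out. The count was 0 without Tert+ RT replicate 1, 2 or 4 or Tert- RT replicate 3, 1 without Tert- RT replicate 4, 7 without Tert+ no RT replicate 1, and 0 without both of the libraries least correlated with their groups, Tert+ RT replicates 3 and 4. Ranges did not overlap for 5.03% of genes, where chance gives 2.86% if the libraries are not paired.

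Of the lists after RT, nuclear encoded respiratory chain genes were higher in Tert+ in 39 of 42 members with 0 past, over all genes or adjusted over the list alone. The respiratory chain list had a camera adjusted p of 8.0e-07, and adjusted p = 0.873 with an estimated correlation. The list's median log2 fold change was 0.20. Ductal keratin and epithelial identity genes were lower in 14 of 17 members with 0 past by either adjustment. The keratin list had a camera adjusted p of 0.0376, and adjusted p = 0.873 with an estimated correlation. Its member Krt18 was at 93.4 ± 46.5 against 106 ± 36.0 CPM. The call ended without Tert+ RT replicate 1 (adjusted p = 0.120) or 4 (0.572) and without Tert- RT replicate 2 (0.0879) or 4 (0.125). Of 24 immune cell genes 0 passed over all genes and 5 fell when adjusted over the list alone, and the list was not called (camera adjusted p = 0.678; fry mixed adjusted p = 0.0192).

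The third comparison asked what RT changed in Tert+ cells. Mef2b, Rgs13, S1pr2 and Gcsam, known from germinal centre B cells, fell. At the preset correlation the cell cycle and cholesterol synthesis lists were called lower and the mitochondrially encoded, p53 target and interferon response lists higher, and none of the 5 was called at an estimated correlation. Mef2b (ENSMUSG00000079033, chromosome 8, 70139711 to 70167488), a transcription factor of germinal centres, fell to 7.30 ± 3.76 against 108 ± 36.6 CPM (SD, n = 4 and 3; adjusted p = 0.00140). Rgs13 and S1pr2, regulators of G protein signalling and migration in germinal centres, fell to 3.81 ± 1.34 against 61.0 ± 28.5 and 3.91 ± 4.66 against 73.9 ± 28.1 CPM. Gcsam, a germinal centre signalling protein, fell to 1.26 ± 1.53 against 55.6 ± 14.1 CPM. Ighg1, an immunoglobulin heavy chain, fell to 1.17 ± 1.36 against 54.9 ± 10.5 CPM. P2ry6 had 3 counts against 247, 27.5-fold to 397-fold lower by its counting interval, and Gatm fell to 1.29 ± 1.88 against 18.3 ± 2.03 CPM.

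The DNA replication and cell cycle list was called lower in Tert+ after RT, with 4 of 42 falling, 1 rising and 37 not past, and 9 falling and 1 rising when adjusted over the list alone. The camera test gave an adjusted p of 2.1e-09, and an adjusted p of 0.106 with an estimated correlation. The replication helicase genes Mcm5 (ENSMUSG00000005410, chromosome 8, 75109569 to 75128439), Mcm6 and Mcm2 fell to 41.7 ± 6.11 against 142 ± 16.7, 53.2 ± 13.1 against 144 ± 35.8 and 56.0 ± 15.7 against 132 ± 1.31 CPM. The centromere gene Cenpa rose to 155 ± 31.0 against 64.5 ± 8.30 CPM. The cholesterol synthesis list was called lower, with 5 of 19 falling and 14 not past, and 5 falling when adjusted over the list alone. The cholesterol list had a camera adjusted p of 1.7e-07, and adjusted p = 0.0584 with an estimated correlation. The synthesis enzymes Sqle and Fdft1 fell to 14.8 ± 8.18 against 57.0 ± 16.7 and 19.8 ± 5.16 against 46.0 ± 7.95 CPM. Of 30 unfolded protein response genes 3 fell and 27 did not pass, with 6 falling and 1 rising when adjusted over the list alone. The unfolded protein list had a camera adjusted p of 0.00127, and adjusted p = 0.112 with an estimated correlation. The 3 past over all genes were Pdia6 at 219 ± 38.2 against 391 ± 68.9 CPM, Creld2 and Sdf2l1. The oxidative stress list of Nrf2 targets was called lower, with 2 of 22 falling, Tkt and Taldo1 of the pentose phosphate pathway, and 3 when adjusted over the list alone. The Nrf2 list had a camera adjusted p of 0.0343, and adjusted p = 0.425 with an estimated correlation. The call ended without Tert+ no RT replicate 1 (adjusted p = 0.138) and Tert+ RT replicates 1 (0.0719) and 3 (0.0571). Of 42 nuclear encoded respiratory chain genes 2 fell over all genes and adjusted over the list alone, Atp5a1 and Uqcrc1. The respiratory chain list had a camera adjusted p of 0.00202, and adjusted p = 0.755 with an estimated correlation.

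The list of mitochondrially encoded transcripts was called higher in Tert+ after RT, with 8 of 15 rising and 7 not past, and 10 rising when adjusted over the list alone. The mitochondrial transcript list had a camera adjusted p of 9.1e-15, and adjusted p = 0.106 with an estimated correlation. The cytochrome oxidase genes mt-Co2 (ENSMUSG00000064354, chromosome MT, 7013 to 7696), mt-Co3 and mt-Co1 rose to 80.8 ± 13.5 against 24.2 ± 8.18, 102 ± 19.9 against 31.8 ± 18.1 and 8339.9 ± 2305 against 2441 ± 1451 CPM. From complex I, mt-Nd4 rose to 855 ± 247 against 239.8 ± 139 CPM. The mitochondrial share of counts was 2.05% after RT and 0.652% without. Of 30 p53 targets 3 rose and 27 did not pass, with 6 rising when adjusted over the list alone. The p53 list had a camera adjusted p of 1.8e-05, and adjusted p = 0.106 with an estimated correlation. Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), the cell cycle inhibitor p21, rose to 62.1 ± 8.44 against 14.3 ± 3.19 CPM (adjusted p = 0.0400). Phlda3 and Ccng1 rose to 13.7 ± 3.11 against 2.39 ± 1.43 and 169 ± 11.2 against 102 ± 4.10 CPM. The interferon response list was called higher, with 3 of 38 rising and 35 not past, and 13 rising when adjusted over the list alone. The interferon list had a camera adjusted p of 9.5e-12, and adjusted p = 0.223 with an estimated correlation. The antiviral GTPase Mx1 rose to 12.3 ± 6.97 against 0.822 ± 0.431 CPM and Xaf1 to 74.8 ± 10.3 against 30.2 ± 8.89 CPM. Of 75 ribosomal protein genes 0 passed and 4 rose when adjusted over the list alone. The ribosomal protein list had a camera adjusted p of 1.0e-09, and adjusted p = 0.744 with an estimated correlation. Immediate early genes had 0 of 28 past and 2 rising when adjusted over the list alone. The immediate early list had a camera adjusted p of 0.0180, and adjusted p = 0.755 with an estimated correlation. That immediate early call ended without Tert+ no RT replicate 3 (adjusted p = 0.299) or Tert+ RT replicate 3 (0.0677). Red blood cell genes had 0 of 5 past and 3 rising when adjusted over the list alone. The red blood cell list had a camera adjusted p of 0.0478, and adjusted p = 0.744 with an estimated correlation. This last call ended without Tert+ no RT replicate 1 (adjusted p = 0.160), Tert+ RT replicates 1 (0.0818), 3 (0.0628) and 4 (0.0916) and Tert- RT replicate 4 (0.0558), and with RLE (0.0553) or upper quartile scaling (0.0702). Of 30 DNA damage repair genes 2 fell, Xrcc6 at 39.6 ± 8.57 against 85.8 ± 13.7 CPM and the histone H2afx at 40.1 ± 2.50 against 93.9 ± 22.2 CPM. On that list 5 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.529; fry mixed adjusted p = 3.5e-11).

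edgeR put 176 genes higher and 139 lower in Tert+ after RT, 315 of 15915, of which 50 were unnamed loci or predicted genes, and ranges did not overlap for 15.7% of genes, where chance gives 5.71%. The count was 22 and 21 without Tert+ no RT replicates 2 and 3, 507 without Tert- no RT replicate 1, 187, 100 and 101 without Tert+ RT replicates 1, 2 and 3, 188 and 192 without Tert- RT replicates 2 and 3, and 53 without both Tert+ RT replicates 3 and 4. A fit of only the groups compared gave 49, a block for the replicate numbers, which pair no samples across RT, 0 (1836 at an unadjusted p under 0.05), DESeq2 1057 and limma voom 1059. The block fit held only the groups compared and the numbers found in both, so Tert+ RT replicate 4 was left out. Its 0 is thus nearer in design to the 49 than to the 315. Of 43 named genes past the threshold, 4 kept their calls in each of the 14 leave-outs, among them Mcm5, Mef2b and P2ry6, and the other 39 lost theirs in at least 1.

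**Figure D3:**
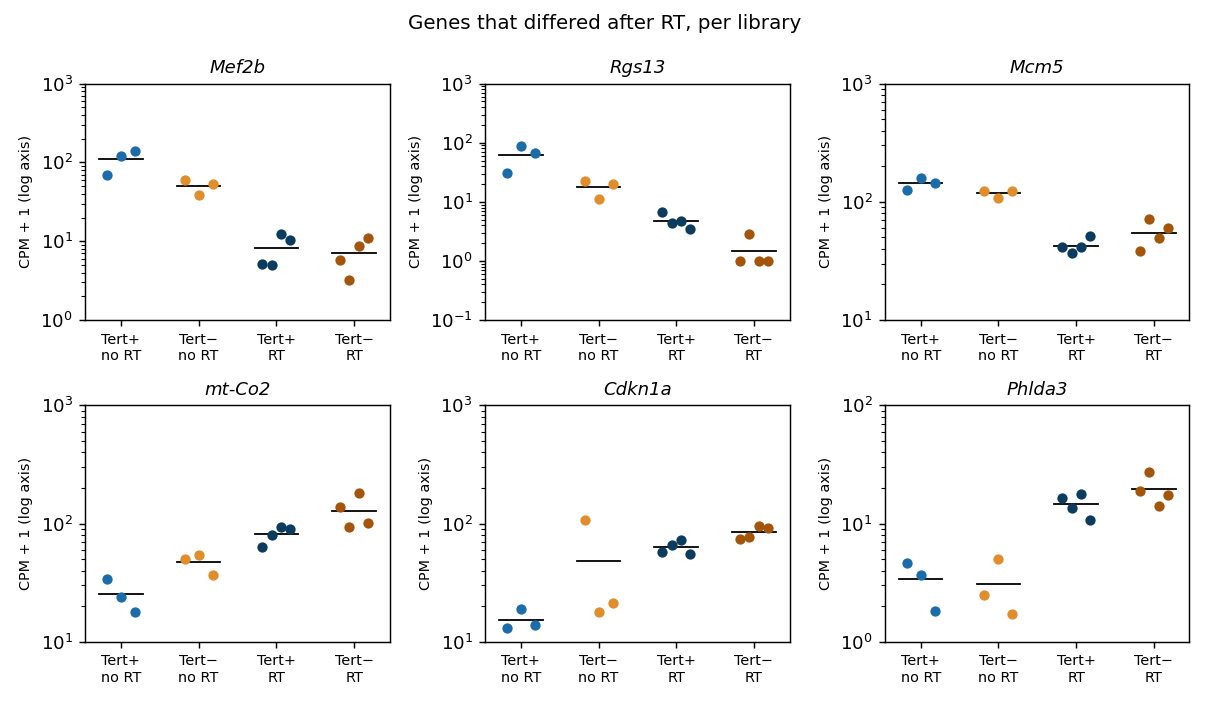
CPM plus 1, on a log axis, of 6 genes that differed after RT in Tert+ libraries, with 1 point per library and a line at each group's mean. Mef2b had means of 7.30 CPM in Tert+ and 6.18 CPM in Tert- after RT, against 108 and 49.6 CPM without.

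The fourth comparison asked what RT changed in Tert- cells. Mef2b and Rgs13 fell here as well. The immune cell and unfolded protein response lists were called lower and the p53 target and ribosomal protein lists higher at the preset correlation, and none of the 4 at an estimated one. Mef2b fell to 6.18 ± 3.43 against 49.6 ± 10.7 CPM (SD, n = 4 and 3; adjusted p = 0.0120) and Rgs13 to 0.454 ± 0.908 against 16.9 ± 5.85 CPM. Ighg1 fell to 1.13 ± 1.53 against 27.8 ± 6.30 CPM and Jchain, the joining chain of secreted antibodies, to 0.594 ± 0.713 against 44.3 ± 29.3 CPM. Basp1 fell to 4.54 ± 1.84 against 36.9 ± 18.9 CPM and Itgae, an integrin subunit, to 1.92 ± 1.14 against 20.7 ± 12.8 CPM (adjusted p = 0.0146 for both). Cdkn1b (ENSMUSG00000003031, chromosome 6, 134920401 to 134925513), the cell cycle inhibitor p27, rose to 50.1 ± 4.22 against 15.0 ± 2.45 CPM (adjusted p = 0.010). The small nucleolar RNA host genes Snhg15 and Snhg1 rose to 74.0 ± 10.4 against 19.1 ± 14.3 and 28.9 ± 6.67 against 7.25 ± 4.88 CPM, and Mdn1, of ribosome assembly, to 103 ± 10.7 against 36.3 ± 14.3 CPM.

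The p53 target list was called higher in Tert- after RT, with 3 of 30 rising and 27 not past, and 3 when adjusted over the list alone. The p53 list had a camera adjusted p of 4.3e-05, and adjusted p = 0.0635 with an estimated correlation. The 3 genes were Phlda3 at 18.4 ± 5.57 against 2.08 ± 1.72 CPM, Ccng1 at 157 ± 18.2 against 96.7 ± 11.1 CPM and Sesn1 at 137 ± 18.3 against 79.4 ± 9.16 CPM. The ribosomal protein list was called higher, with 74 of 75 members not past and 1 rising, Rpl12 at 337 ± 53.2 against 194 ± 17.3 CPM, and 41 rising when adjusted over the list alone. The ribosomal protein list had a camera adjusted p of 5.7e-19, and adjusted p = 0.438 with an estimated correlation. Of 15 mitochondrially encoded transcripts 2 rose, mt-Co2 to 128 ± 40.0 against 46.0 ± 9.35 CPM and mt-Co3 to 128 ± 32.8 against 51.6 ± 5.29 CPM. Adjusted over the list alone, 8 rose. The mitochondrial transcript list had a camera adjusted p of 4.4e-06, and adjusted p = 0.438 with an estimated correlation. The mitochondrial share of counts was 2.28% after RT and 1.12% without. Interferon response genes had 0 of 38 past and 4 rising when adjusted over the list alone. The interferon list had a camera adjusted p of 1.6e-04, and adjusted p = 0.679 with an estimated correlation. Of 22 fluid secretion genes 1 rose, and the list was not called (camera adjusted p = 0.693).

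The immune cell list was called lower in Tert- after RT, with 23 of 24 members not past and 1 falling, the receptor subunit Fcer1g at 32.5 ± 16.6 against 127 ± 12.8 CPM, and 7 falling when adjusted over the list alone. The immune cell list had a camera adjusted p of 4.5e-07, and adjusted p = 0.0635 with an estimated correlation. The unfolded protein response list was called lower, with 3 of 30 falling and 27 not past, and 10 falling and 1 rising when adjusted over the list alone. The unfolded protein list had a camera adjusted p of 4.3e-05, and adjusted p = 0.0635 with an estimated correlation. Sdf2l1, Dnajb11 and Pdia6 fell to 34.9 ± 9.0 against 87.4 ± 16.8, 90.2 ± 10.6 against 159 ± 24.5 and 213 ± 26.9 against 366 ± 50.4 CPM. The cholesterol synthesis list was called lower too, with 3 of 19 falling, 16 not past and 7 falling when adjusted over the list alone. The cholesterol list had a camera adjusted p of 1.9e-06, and adjusted p = 0.0635 with an estimated correlation. Among the 3 past the threshold were Sqle at 17.0 ± 4.84 against 62.0 ± 13.2 CPM and Msmo1 at 24.3 ± 2.63 against 66.0 ± 20.2 CPM. The cell cycle list was called lower, with 40 of 42 members not past and 2 falling, Mcm5 at 53.8 ± 14 against 117 ± 8.56 CPM and Mcm6 at 48.0 ± 14.3 against 124 ± 24.9 CPM. Adjusted over the list alone, 11 fell and 1 rose. The cell cycle list had a camera adjusted p of 1.8e-06, and adjusted p = 0.189 with an estimated correlation. Of 42 nuclear encoded respiratory chain genes 3 fell, Uqcrc1 and Sdha among them, and 8 when adjusted over the list alone. The respiratory chain list had a camera adjusted p of 2.8e-07, and adjusted p = 0.505 with an estimated correlation. The Nrf2 list was called lower, with 1 of 22 falling and 3 when adjusted over the list alone. The Nrf2 list had a camera adjusted p of 0.00281, and adjusted p = 0.189 with an estimated correlation. The member past the threshold was the cystine transporter Slc7a11, with 3 counts against 389, 41.3-fold to 592-fold lower by its counting interval. Of 18 salivary progenitor genes 2 fell, over all genes and adjusted over the list alone, Cd44 at 37.1 ± 8.17 against 81.1 ± 33.7 CPM and Itgb1 at 74.6 ± 6.66 against 143 ± 34.0 CPM. The list itself was not called (camera adjusted p = 0.693). Granular convoluted tubule genes had 0 of 20 past by either adjustment. The tubule list had a camera adjusted p of 9.1e-04, and adjusted p = 0.816 with an estimated correlation. Its call ended without Tert- no RT replicate 2 (adjusted p = 0.0810). Acinar genes had 0 of 18 past by either adjustment. The acinar list had a camera adjusted p of 0.0270, and adjusted p = 0.871 with an estimated correlation. The acinar call ended without Tert- no RT replicates 1 (adjusted p = 0.0670) and 3 (0.169) and Tert- RT replicate 2 (0.0825).

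edgeR put 130 genes higher and 128 lower in Tert- after RT, 258 of 15915, of which 33 were unnamed loci or predicted genes, and ranges did not overlap for 18.9% of genes, where chance gives 5.71%. The count was 416 and 123 without Tert+ no RT replicates 1 and 2, 901, 19 and 18 without Tert- no RT replicates 1, 2 and 3, and 111, 60, 21 and 73 without Tert- RT replicates 1 to 4. With only the groups compared it was 88, with the replicate block 0 (2313 at an unadjusted p under 0.05), with DESeq2 1198 and with limma voom 1371. The block fit again held only the groups compared and left out Tert- RT replicate 4. Of 36 named genes past the threshold, 3 kept their calls in each of the 14 leave-outs, Cdkn1b and Mef2b among them, and the other 33 lost theirs in at least 1.

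The RT changes in Tert+ and Tert- libraries shared 69 genes that rose and 47 that fell, where independent lists would share 1.44 and 1.12 by the product of their sizes over the genes tested. Shared falls included Mef2b, Rgs13, Ighg1, Mcm5, Mcm6 and Sqle, and shared rises mt-Co2, mt-Co3, Ccng1, Phlda3 and Cdkn1b. No gene was past in both with opposite directions. Of the 315 genes past in Tert+, 310 had the same sign in Tert-, and of the 258 past in Tert-, 257 had the same sign in Tert+. The log2 fold changes correlated at r = 0.773 across the 457 genes past in either and at 0.359 across all genes tested, and genes are not independent replicates. The pair of comparisons used different libraries but the same fit, in which each gene's spread was estimated over all 14 libraries. Genes with a small spread could pass more easily in both, so the numbers for independent lists are too low a measure. Without RT, replicates 1 and 2 also correlated best with their own number in the other population. The comparisons were therefore not fully independent. All libraries after RT were also numbered after those without, so library batch and RT cannot be told apart.

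**Figure D4:**
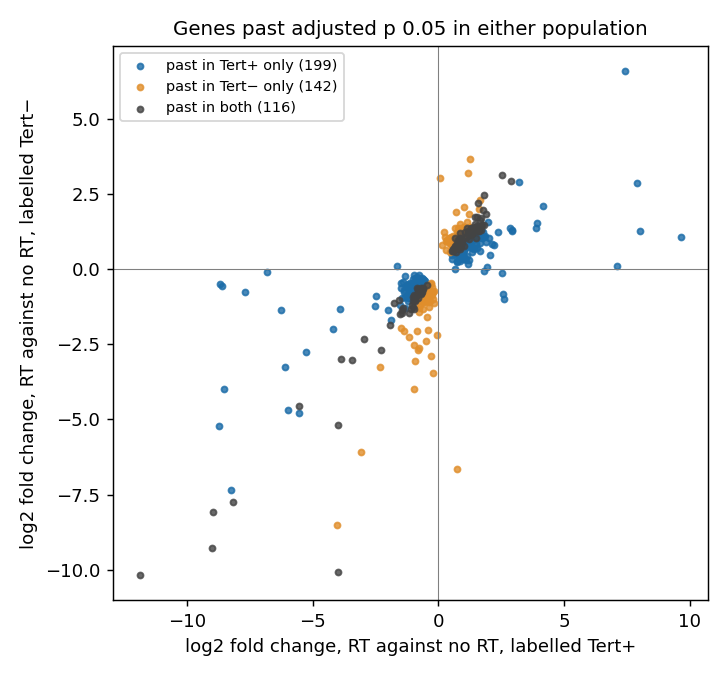
Log2 fold change of RT against no RT in Tert+ libraries (horizontal axis) and in Tert- libraries (vertical axis), 1 point per gene past the threshold in either. 116 genes were past in both, 199 in Tert+ alone and 142 in Tert- alone.

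The fifth comparison asked whether RT changed Tert+ and Tert- cells differently. edgeR put 0 of 15915 genes past the threshold, with 578 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00, while DESeq2 called 12 and limma voom 0. The genes with the smallest unadjusted p, none past, were Sema3b, Ms4a7, Pls3, Slc22a23 and Slc7a11, and Ms4a7 had a log2 difference of 3.38 (SE 0.74). This SE was computed as the difference over the square root of its F statistic. Of the lists, 7 were called at the preset correlation and had 0 members past by either adjustment. Granular convoluted tubule genes had a higher RT effect in Tert+ in 20 of 20 members (camera adjusted p = 2.6e-10), as did 21 of 24 immune cell genes (2.4e-04) and 16 of 19 senescence and secreted inflammatory factors (0.00410). The same direction held for 28 of 38 interferon response genes (0.00126), 14 of 15 mitochondrially encoded transcripts (7.6e-04) and 30 of 42 nuclear encoded respiratory chain genes (0.0477). Ribosomal protein genes had a lower RT effect in Tert+ in 67 of 75 members (0.00308). With an estimated correlation the adjusted p was 0.642 for the immune list and 0.906 for the other 6. The senescence call ended without Tert- no RT replicate 1 (0.745). The interferon call ended without Tert+ no RT replicate 1 (0.198), Tert+ RT replicate 1 (0.216) or Tert- RT replicate 4 (0.203). The mitochondrial call ended without Tert+ no RT replicate 3 (0.141) or Tert- RT replicate 4 (0.124). The ribosomal call ended without Tert+ no RT replicate 1 (0.703), Tert+ RT replicate 1 (0.505) or Tert- RT replicate 1 (0.650). The respiratory chain call held in 6 of 14 leave-outs, with an adjusted p of up to 0.837, reached without Tert- no RT replicate 3, and 0.0631 with upper quartile scaling.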

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

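The tests on immune cell lists, on T cell and macrophage scores, on the population labels, on library numbers and on calls kept after thinning were chosen after the result was seen.

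B lymphocyte genes stood above Epcam, Krt8 and Krt18 in libraries sorted on EpCAM, though the gland's acinar genes also took a median of 1.13% of counts. A candidate explanation is lymphocytes among the sorted cells: 13 of 13 tested members of a mature B cell list had a mean log2 CPM above that of Epcam, and the list took a median of 1.08% of counts. Its most abundant members, Ighd, Fcer2a and Bank1, had mean log2 CPM of 11.52, 10.30 and 10.22, 0 of the 13 are on another list, and lymphocytes lack EpCAM, so the EpCAM gate would remove them. Whether they passed the gate, or RNA from other cells entered the libraries, was not tested. No biological explanation was tested, since the design names none for this pattern.

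Genes known from macrophages, such as C1qc and Ms4a7, were lower in Tert+ libraries without RT, and more macrophages in the Tert- libraries may account for it. A list of 16 macrophage genes, written after the gene tables had been seen, had an adjusted p of 0.0109 with an estimated correlation but held Csf1r and Adgre1, already seen to fall; without these, 13 of 14 were lower, 5 of them past when adjusted over the list alone, with a median log2 fold change of -1.38 and an adjusted p of 0.0192. Of the most abundant members left, Lgmn had a log2 fold change of -0.76, while Ctsb (-0.31) and Ctsd (-0.01), which B cells and epithelium also express, differed little. Lyz2 went the other way. The EpCAM gate should remove macrophages, but B lymphocyte genes stood above Epcam in these gated libraries, so the gate does not decide this. A lower share of the main cell type in the Tert- libraries would raise T cell and macrophage genes there alike. The T cell score minus the macrophage score differed by 1.91 (SE 0.861) between the groups and by 1.97, 2.28 and 1.48 within the numbers. The macrophage score was taken over all 16 genes, Csf1r and Adgre1 among them. These gaps do not decide on that lower share, since the macrophage list was written after macrophage genes had been seen to fall here. A gap to the T cell score was therefore likely from the start. Pairing by number is also not settled, and without it the library values (1.78, 0.17 and -0.28 against -0.18, -2.12 and -1.75) overlap. As that explanation needs, 10 of 10 fibroblast, 20 of 20 granular convoluted tubule and 6 of 8 endothelial genes were lower in Tert+ too. Other lists went the other way, with 14 of 18 acinar and 10 of 10 T cell genes higher in Tert+. The acinar share of counts was 1.60% in Tert+ and 1.47% in Tert- (exact permutation p = 0.9), and Tert+ replicate 1 reached 3.89%. The lists thus disagree, and with this spread they do not decide on a lower share of the main cell type. An exchange of population labels and a true difference between the populations cannot be told apart. Without RT, Tert itself ran against the titles at the smallest p that 3 against 3 libraries allow (exact permutation p = 0.1). After RT it ran with the titles at 3.58 against 0.621 CPM (exact permutation p = 0.257). There 14 of 16 macrophage genes were again lower in Tert+. An exchange without RT alone would give the opposite order, if RT left the order as it was. However, the macrophage list without Csf1r and Adgre1 had a camera adjusted p of 0.200 after RT with an estimated correlation. An exchange in all 14 libraries, as the cell type field would have it, gives the same order with and without RT. The macrophage order cannot bear on that exchange. A true difference stays open, untested.

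After RT, in Tert+ and in Tert-, the germinal centre genes Mef2b and Rgs13 fell, 4 and 2 of 42 cell cycle genes fell, and 8 and 2 of 15 mitochondrially encoded genes rose, while camera with an estimated correlation called neither list (adjusted p = 0.106 and 0.189 for cell cycle and 0.106 and 0.438 for mitochondrially encoded genes). An offset for GC content and gene length kept 88.8% of the median absolute log2 fold change of 313 genes called in Tert+. That argues against such bias as the whole cause of the size of the changes over these called genes. With the offset, however, 145 of the 315 genes passed again in Tert+ and 199 of the 258 in Tert-. The 88.8% was not taken over the germinal centre, cell cycle or mitochondrially encoded genes alone, so a part played by this bias stays open. Tables argue against unequal library size, since 292 of the 315 genes passed again with each library thinned to the smallest total. The 99.8% of fold change kept there decides nothing, since folds are scaled for depth. Fewer germinal centre B cells after RT may account for the germinal centre part, but this stays open: a list of 8 genes, written after the gene tables had been seen, had a larger adjusted p of 0.0132 over the 2 populations with an estimated correlation and held Rgs13 and S1pr2, already seen to fall, and without these the adjusted p was 0.00501 in Tert+ and 0.0527 in Tert-. Its most abundant members, Lmo2 and Bcl6, had log2 fold changes of -0.64 and -1.01 in Tert+, and 0 of the 8 are on another list. Bcl6 was itself past the threshold in edgeR in Tert+ (adjusted p = 0.0238) and in Tert- (0.0327). It stayed on the shortened list, which is therefore not free of genes that could be seen to fall before it was written. The EpCAM gate should remove such cells, but B lymphocyte genes stood above Epcam in these gated libraries, so the gate does not decide this. Library batch and RT cannot be told apart, because 0 libraries after RT carry a number below the highest without RT, and a direct effect of RT on the sorted cells stays open, untested.

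Other splits of the same samples were counted for each comparison. Without RT, in Tert+ against Tert- libraries, 1 of 10 splits gave as many genes as the real 6, the real split itself, and the highest of the others gave 1; 10 splits are too few for a share under 0.05. Among the splits that part the 3 number pairs, the other 3 gave 0. In 3 comparisons 1 of 35 splits, the real split, gave as many, the smallest share these splits can give. For RT in Tert+ the real count was 315 and the highest other 1, and for RT in Tert- 258 and 0. Chance placing of these libraries is thus an unlikely source of those counts. The other RT splits mix libraries with and without RT, which widens the spread within groups and can lower their counts. For Tert+ against Tert- after RT the real count was 2 and the highest other 1. A margin of 1 gene is too small to exclude chance there, and neither gene kept its call in each leave-out. For the difference of the RT effects, where the real count was 0, 100 of 100 splits gave as many, which a count of 0 fixes in advance, so the splits decide nothing there; the highest gave 27, more than the real split.

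A library lay far from the other 3 of its group in 10 of 150 values tested after RT, and chance alone gives about 1 in 20. The number given for each of the 9 reported here is its gap to the nearest library as a share of the group's range. In Tert+ after RT, replicate 1 stood apart for P2ry6 (1; 0.261 against 0 CPM in the others) and Xrcc6 (0.909; 52.4 against 34.7 to 36.3 CPM). Replicate 3 stood apart there for Gatm (0.894; 4.09 against 0.0871 to 0.513 CPM) and Cep295 (0.845; 36.0 against 23.8 to 25.7 CPM). In Tert- after RT, replicate 4 stood apart for Ccng1 (0.923; 129.8 against 165 to 168 CPM) and mt-Nd4 (0.917; 515 against 1080.1 to 1131 CPM). Replicate 2 stood apart there for Rgs13 (1; 1.82 against 0 CPM), Gcsam (1; 2.08 against 0 CPM) and the granular convoluted tubule share of counts (0.951; 1.28% against 0.218% to 0.270%).

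The effect of RT differed between Tert+ and Tert- libraries in 7 gene lists by the test of the difference at a preset correlation. The adjusted p was 2.6e-10 for granular convoluted tubule genes, 2.4e-04 for immune cells, 7.6e-04 for mitochondrially encoded transcripts, 0.00126 for the interferon response, 0.00308 for ribosomal proteins, 0.00410 for senescence and secreted inflammatory factors and 0.0477 for the nuclear encoded respiratory chain. With an estimated correlation the adjusted p was 0.642 for immune cells and 0.906 for the other 6.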

How the results depend on the processing

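Without the 2 least correlated libraries, without acinar and granular convoluted tubule genes, with the epithelial covariate and with the GC and length offset are alternatives chosen after seeing the data. Numbers of genes past the threshold moved by over 1.5 times as follows, and the cause was not tested except where fewer libraries, the fold demanded or a preset against an estimated correlation give it. For Tert+ against Tert- without RT (6), the count was 16 with no filter, 12 thinned, 16 without the 2 least correlated libraries, 10 with the epithelial covariate, 3 with the GC and length offset, 74 with DESeq2, 33 with voom, 3 with a test against 1.5-fold and 1 to 13 over the leave-outs. For the same after RT (2), it was 4 with no filter, 0 without the 2 least correlated libraries, 109 with DESeq2, 0 with voom, 1 against 1.5-fold, 1 with only the groups compared, 1 with the replicate block and 0 to 7 over the leave-outs. For RT in Tert+ (315), it was 53 without the 2 least correlated libraries, 162 with the GC and length offset, 1057 with DESeq2, 1059 with voom, 12 against 1.5-fold, 49 with only the groups compared, 0 with the replicate block and 21 to 507 over the leave-outs. For RT in Tert- (258), it was 1198 with DESeq2, 1371 with voom, 5 against 1.5-fold, 88 with only the groups compared, 0 with the replicate block and 18 to 901 over the leave-outs. For the difference of the RT effects (0), it was 12 with DESeq2 and 0 to 1 over the leave-outs; a fit of only the groups compared does not exist there, since it uses all 4. The other settings stayed within 1.5 times. Lists called with an estimated correlation numbered 0 in each of the 5 comparisons, where the preset gave 9, 2, 11, 12 and 7. fry called 0 in Tert+ against Tert- without RT, 0 after RT and 0 for the difference of the RT effects, and its mixed test called 1 without RT and 0 for the difference. Over the leave-outs, lists called ran from 5 to 16 without RT, from 1 to 6 after RT, from 8 to 13 for RT in Tert+, from 12 to 17 for RT in Tert- and from 4 to 12 for the difference. With a block for the replicate numbers, 6 lists were called after RT. For RT in Tert+ and in Tert-, the block fit held only the groups compared and left out replicate 4 of the RT group. Replicate numbers may pair the samples without RT, where replicate 3 correlated better with another number. After RT the same-number correlations were 0.0943, 0.116, 0.0837 and 0.0329. There replicates 1 to 3 correlated best with their own number and replicate 4 did not, so pairing is not settled there either. Across RT the correlations were -0.0243, -0.144 and -0.0895 in Tert+ and 0.0599, 0.0670 and -0.0856 in Tert-, so those libraries only share a number. Of 2782 values of named genes recomputed, 2060 kept their side of the threshold, 708 fell short of it, 14 newly passed and 0 changed direction. No scaling moved the median log2 fold change of all genes by over 0.1, though upper quartile scaling raised the share of higher calls from 55.9% to 67.9% for RT in Tert+ and from 50.4% to 65.9% in Tert-. At a depth of 5520412 to 15943597 counts a library, Tert had at most 52 counts, and genes at 0 in a group have folds that are bounds.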

Other observations

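The tests on the 7 immune cell lists below were chosen after the result was seen. The mature B cell list, at a median of 1.08% of counts, was not called by camera in any comparison, with an estimated-correlation adjusted p of 0.994 for Tert+ against Tert- without RT, 0.966 after RT, 0.990 and 0.988 for RT in Tert+ and in Tert-, and 0.971 for the difference of the RT effects. Of its 13 members 1 rose with RT in Tert-, 1 rose in Tert+ when adjusted over the list alone, and the fry mixed adjusted p was 0.00620 in Tert+ and 0.0275 in Tert-. Germinal centre genes had a median log2 fold change of -1.98 with RT in Tert+ (4 of 8 fell, 7 adjusted over the list alone; adjusted p = 0.00167 with an estimated correlation) and -1.05 in Tert- (2 fell, 4 adjusted over the list alone; 0.0132). This list held Rgs13 and S1pr2, already seen to fall, and without them the adjusted p was 0.00501 and 0.0527. Bcl6, past the threshold in both populations, stayed on the shortened list. For Tert+ against Tert- the list had 0.168 without RT and 0.802 after RT, where 1 member rose and 1 fell when adjusted over the list alone and the fry mixed adjusted p was 0.00147, and the difference of the RT effects gave 0.249. The macrophage list was lower with RT in Tert-, with a median of -0.95 (1 of 16 fell, 6 adjusted over the list alone; 0.0433, or 0.0527 without Csf1r and Adgre1), and had 0.243 with RT in Tert+, 0.0921 for Tert+ against Tert- after RT and 0.538 for the difference. Monocyte and neutrophil genes were higher in Tert+ after RT in 10 of 10 members, with a median of 2.45 (1 rose, 2 adjusted over the list alone; 0.0885); the list includes Ly6c2, which had been seen before it was written. With RT in Tert- 9 of its 10 members were lower, with a median of -2.12 (1 fell, 5 adjusted over the list alone; 0.282, fry mixed 0.0193). That list had 0.788 without RT, 0.990 for RT in Tert+ and 0.249 for the difference.

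T cell genes were lower after RT in 10 of 10 members in Tert+ and in Tert-, with medians of -0.77 and -1.82, and 0 of 10 passed (adjusted p = 0.514 and 0.284 with an estimated correlation). Their adjusted p was 0.788 for Tert+ against Tert- without RT, 0.365 after RT and 0.971 for the difference. Dendritic cell genes had medians of -1.31 and -1.58 with RT in Tert+ and in Tert- (0.114 and 0.109), 0.948 and 0.802 for Tert+ against Tert- without and after RT, and 0.971 for the difference. Plasma cell genes had 0.168 without RT, 0.365 after RT, 0.247 and 0.287 for RT in Tert+ and in Tert-, and 0.971 for the difference. Of the list members, 2 of 16 macrophage, 3 of 10 T cell, 1 of 10 dendritic cell and 3 of 10 monocyte and neutrophil genes are also on a list fixed earlier, and 0 are on another of the 7.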
